A study of Homo sapiens with 6 samples.

How the data were processed

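Poly(A)-selected RNA of HSC6 cells, an established human oral squamous cell carcinoma line, was sequenced from 3 control libraries and 3 libraries treated with GSK591, a small-molecule inhibitor of the arginine methyltransferase PRMT5. Per the labels' protocols, the RNA was fragmented, copied with random hexamers, size-selected with beads and amplified by PCR. The protocol names no step that marks the strand. The dose, the time of treatment, the vehicle, and the aligner and counter are not given in the sources used here. Per the submitters' processing notes, the genome build was GRCh38.

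The authors deposited 1 table of 20307 genes, which holds an expected count and a TPM value (transcript abundance scaled to a fixed library total) for each gene and library. The deposited expected counts are estimated reads per gene with no scaling. They were not whole numbers for 14.4% to 14.7% of the detected genes, as can happen where reads that match several genes are divided by an estimate. How such reads were treated is not given in the sources used here, so values of near-identical copies, of overlapping genes and of genes on opposite strands are uncertain. The deposited TPM values sum to the same total in every library and depend on the transcript lengths that the authors' tool used. Symbols, pathways and ontology terms came from the same table, and 605 genes had no symbol.

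The design written before the data were examined named gene counts, and the expected counts were rounded to whole numbers for it. Genes were kept with filterByExpr, which left 12491 of the 20307 genes, and 7816 were not tested. Libraries were scaled by TMM. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust dispersion compared GSK591 with control, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log2 fold changes are GSK591 over control, and levels are CPM (counts scaled by effective library size) as mean ± SD over 3 libraries. Standard errors were derived from the fold change and the F statistic. Total counts were 15844294, 14710415 and 16692865 in control replicates 1, 2 and 3, and 13806410, 17349332 and 14743184 in GSK591 replicates 1, 2 and 3. The biological coefficient of variation was 11.9%. On simulated counts with 200 changed genes among 12341, the same steps recovered 57% of the genes changed 1.5-fold and 89% of those changed 2-fold. Of the calls, 6.41% were false. The changed genes were drawn only from those above a minimum mean count, and all genes were simulated as independent of each other.

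Gene lists, 36 in number with 1130 entries of which 1127 matched a symbol, were fixed before the data were examined. They covered nucleotide metabolism, FOXM1 targets, cell cycle, repair, stress, splicing, translation, squamous differentiation, inflammation, lipid and energy metabolism and markers of other cell types. Each was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, against all other tested genes, adjusted over the 36 lists. Camera was repeated with an estimated correlation, and fry tested whether the members of a list moved one way without a comparison to other genes. Pathway and ontology terms of 10 to 300 tested genes (3039 terms) were tested with camera at both correlations, in the main fit alone and without fry. A member rose or fell where it passed the gene test over all tested genes. Some lists share members, such as SLC7A11 in the stress response and NRF2 lists and BAX in the p53 and apoptosis lists. The lists are therefore not independent.

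The genes named in the text follow a rule fixed before the data were examined. It takes PRMT5 and FOXM1, and the 10 largest rises and 10 largest falls among genes with a symbol that is no clone name, an adjusted p under 0.05, a mean of at least 50 counts in the higher group and groups that do not overlap. It takes up to 3 risers and 3 fallers of each list with the smallest adjusted p, up to 6 for the pyrimidine and FOXM1 lists, and the members of the de novo pyrimidine and thymidylate routes whatever their test. Gene positions, exon overlaps, transcript numbers, intron lengths and GC content came from GENCODE 29 on GRCh38, to which 20092 of the 20307 identifiers matched. Whether the authors counted on this release is not given in the sources used here. Overlaps were found with bedtools 2.31.1, and tables were handled in Python 3.11.15 with pandas 2.3.3.

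The alternatives were DESeq2 size factors and upper-quartile scaling in the edgeR fit, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, the Wald test of DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and on log2(TPM + 0.1), and each library left out in turn. A fit with a smooth trend of log counts on GC content removed within each library (lowess span 0.3) was added after the data were seen. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. No 2 libraries agreed within sampling noise: the closest pair, control replicates 1 and 2, had a chi-square of 4.95 per degree of freedom.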

Results

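Gene expression was measured in HSC6 cells, a human oral squamous cell carcinoma line, with and without GSK591, which inhibits the arginine methyltransferase PRMT5. There were 3 control and 3 GSK591 libraries, with total counts between 13806410 and 17349332 per library. The comparison addresses how inhibition of PRMT5 bears on the transcription factor FOXM1 and on the genes of pyrimidine metabolism, which the title of the series names. On the first principal component, with 58.1% of the variance, the 3 control libraries lay between -34.0 and -23.6 and the 3 GSK591 libraries between 25.9 and 30.8. The second component, with 16.8%, set control replicate 3 (-27.2) apart from control replicates 1 and 2 (20.3 and 11.3).

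FOXM1, a transcription factor of genes used in G2 and mitosis, fell from 239 ± 7.46 CPM in control cells to 128 ± 21.2 CPM with GSK591 (SD, n = 3 each), a level 1.86-fold lower. Its log2 fold change was -0.90 (SE 0.11) with an adjusted p of 2e-04 in the edgeR quasi-likelihood test. PRMT5 itself rose from 124 ± 7.23 to 153 ± 7.19 CPM, a log2 fold change of 0.30 (SE 0.08, adjusted p = 0.02 in the same test). The PRMT5 log2 fold change did not pass without control replicate 2 (0.27, adjusted p = 0.096), GSK591 replicate 1 (0.28, adjusted p = 0.097) or GSK591 replicate 2 (0.27, adjusted p = 0.076). PRMT5 (ENSG00000100462) lies on chromosome 14 from 22920511 to 22929585 on the minus strand of GRCh38, and its exons overlap those of PRMT5-AS1 on the opposite strand. FOXM1 (ENSG00000111206) lies on chromosome 12 from 2857681 to 2877155, also on the minus strand, with exons that overlap those of ITFG2 on the opposite strand. Reads of such partners cannot be told apart where strand is not marked.

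Genes of pyrimidine metabolism fell more often than they rose. Of the 43 tested members, 17 fell, 4 rose and 22 did not pass, and adjusted over the list alone 17 fell and 5 rose. Without GSK591 replicate 3, 12 fell. CAD, the enzyme that starts de novo pyrimidine synthesis, fell from 97.0 ± 3.53 to 43.4 ± 5.19 CPM (log2 fold change -1.16, SE 0.11). RRM2, a subunit of ribonucleotide reductase, fell from 170 ± 40.2 to 47.6 ± 10.4 CPM (-1.83, SE 0.19), and the thymidine kinase gene TK1 fell from 125 ± 9.16 to 54.0 ± 8.97 CPM (-1.21, SE 0.12). The nucleotidase gene NT5C (-1.48), the thymidylate kinase gene DTYMK (-0.77), the dNTP hydrolase gene SAMHD1 (-0.72), the thymidylate synthase gene TYMS (-0.78) and the CTP synthase gene CTPS1 (-0.66) also fell, with adjusted p between 2.6e-05 and 0.002 for these and the genes above in the edgeR quasi-likelihood test. Exons of NT5C, SAMHD1 and TYMS overlap those of ARMC7, TLDC2 and ENOSF1 on the opposite strand, so their values are uncertain. TYMS is also in the serine and one-carbon list. Genes of DNA replication fell too (31 of 49), and whether the pyrimidine genes fell apart from them was not tested.

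Other members of the route did not pass or rose. DHODH, the dehydrogenase of the de novo route, had 6.12 ± 0.80 CPM in control and 5.81 ± 0.38 CPM with GSK591 (log2 fold change -0.08, adjusted p = 0.78). UMPS, which makes UMP, had a log2 fold change of 0.21 (adjusted p = 0.2), the ribonucleotide reductase gene RRM1 -0.08 (adjusted p = 0.72) and the dUTPase gene DUT -0.23 (adjusted p = 0.13). None of these 4 passed the edgeR quasi-likelihood test, though RRM1 passed without control replicate 3 (-0.27, adjusted p = 0.011) and DUT with the GC correction (-0.30, adjusted p = 0.025). The members that rose were NT5C2 (0.43), NT5E (0.52), UPP1 (0.42) and RRM2B (0.93), a p53-induced ribonucleotide reductase subunit. The sign for RRM2B turned with the deposited TPM values (-0.18), and UPP1 did not pass without control replicate 2 (adjusted p = 0.058) or GSK591 replicate 2 (adjusted p = 0.051). Against all other genes the list was lower in camera with an adjusted p of 0.00404, which was lost at an adjusted p = 0.707 with an estimated correlation. Of the 10 lists that passed camera, none held with an estimated correlation.

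**Figure D1:**
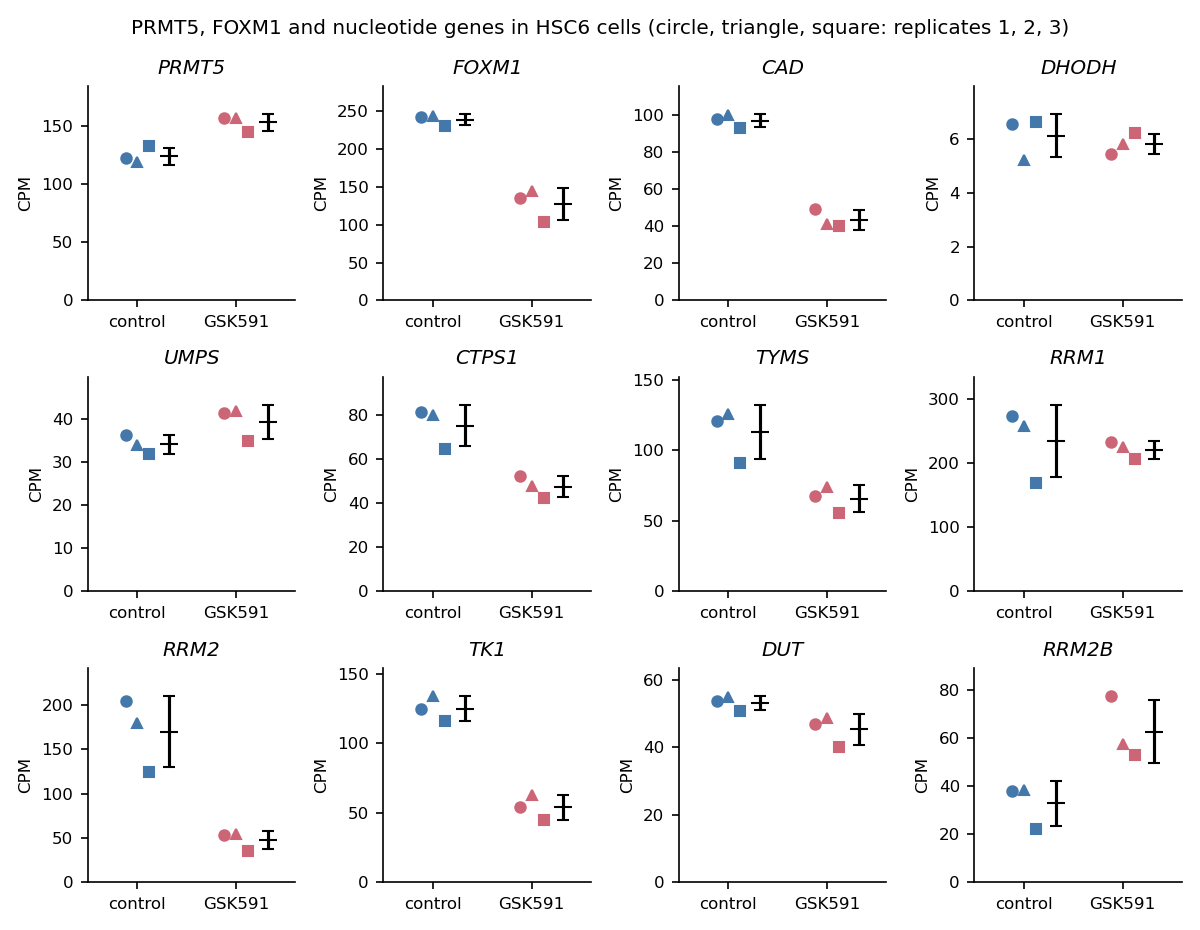
Levels in CPM of PRMT5, FOXM1 and 10 nucleotide genes in each library of control and GSK591-treated HSC6 cells, with black bars for mean ± SD of 3 libraries and axes that start at 0. FOXM1, CAD, RRM2 and TK1 were lower in every GSK591 library than in every control library, while DHODH and RRM1 overlapped.

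Targets of FOXM1 used in G2 and mitosis were lower with GSK591. Of the 56 tested, 29 fell, 1 rose and 26 did not pass, and adjusted over the list alone 30 fell and 1 rose. The mitotic kinase gene AURKB fell from 45.6 ± 2.36 to 16.6 ± 2.15 CPM (log2 fold change -1.45, SE 0.13), and the kinesin gene KIF20A fell from 46.2 ± 8.27 to 15.1 ± 3.09 CPM (-1.61, SE 0.17). CDCA3 (-1.26), PIMREG (-1.12), CDKN3 (-0.97) and the proliferation marker gene MKI67 (-0.71) fell as well, all with an adjusted p of at most 0.00093 in the edgeR quasi-likelihood test. Exons of KIF20A, CDCA3 and PIMREG overlap those of CDC23, GNB3 and PITPNM3 on the opposite strand. The 1 gene that rose, the checkpoint gene BUB3 (0.26, adjusted p = 0.032), did not pass without control replicate 2, without any 1 of the GSK591 replicates or with the GC correction. The camera adjusted p of the list was 2.77e-06, against an adjusted p = 0.817 with an estimated correlation. On the deposited TPM values 19 fell with limma on log2(TPM + 1).

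Genes of DNA replication and the G1/S step were lower as well, and 31 of 49 fell, or 40 adjusted over the list alone, while 18 did not pass. The median log2 fold change was -0.55 in this list and -0.39 in the FOXM1 list, so the fall was not particular to FOXM1 targets. An effect through FOXM1 cannot be told apart here from a general fall of cell-cycle genes. POLD1 (58.7 ± 4.22 to 25.8 ± 1.34 CPM, log2 fold change -1.19), POLA2 (-1.19) and GINS4 (-1.91), which code for parts of the replication machinery, were among the genes that fell. Of 36 genes of homologous recombination and the Fanconi anaemia pathway, 11 fell, among them FANCA (-1.48), XRCC3 (-1.21) and FANCL (-1.04), and 2 rose, RAD50 (0.58) and RAD51C (0.37), with the same counts adjusted over the list alone. RAD50 did not pass without control replicate 2 or GSK591 replicate 3 (adjusted p = 0.064 and 0.11) or on the TPM values, and the RAD51C log2 fold change did not pass without control replicate 2 (0.11) or GSK591 replicate 1, 2 or 3 (0.078, 0.11 and 0.061). Camera adjusted p were 4.87e-12 for the replication list and 0.0345 for the repair list, and both were lost with an estimated correlation (adjusted p = 0.707 and 0.83). Exons of FANCA, XRCC3 and FANCL overlap those of ZNF276, KLC1 and VRK2 on the opposite strand.

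Control replicate 3 lay towards the GSK591 libraries in the FOXM1 and replication lists and below all of them in the repair list. The median log2 CPM of the FOXM1 targets, relative to the mean of the 6 libraries, was 0.39, 0.23 and -0.09 in control replicates 1, 2 and 3 and -0.16, -0.19 and -0.21 in the GSK591 libraries. FOXM1 itself was at 242, 244 and 230 CPM in control replicates 1, 2 and 3. The lower median of its targets in control replicate 3 thus came without a like fall in FOXM1 mRNA. The replication list gave 0.45, 0.36 and 0.07 against -0.21, -0.18 and -0.49. The repair list gave 0.35, 0.19 and -0.21 against 0, -0.16 and -0.16, so its medians did not separate the groups. Without control replicate 3, 38 FOXM1 targets, 41 replication genes and 18 repair genes fell. Without GSK591 replicate 1 or 3, 17 and 18 FOXM1 targets fell. Replication fallers numbered 22 without GSK591 replicate 3, and repair fallers 9 without GSK591 replicate 1 or 3. The repair list did not pass without control replicate 1 (adjusted p = 0.299), control replicate 2 (0.0624), GSK591 replicate 2 (0.0592) or GSK591 replicate 3 (0.0651).

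**Figure D2:**
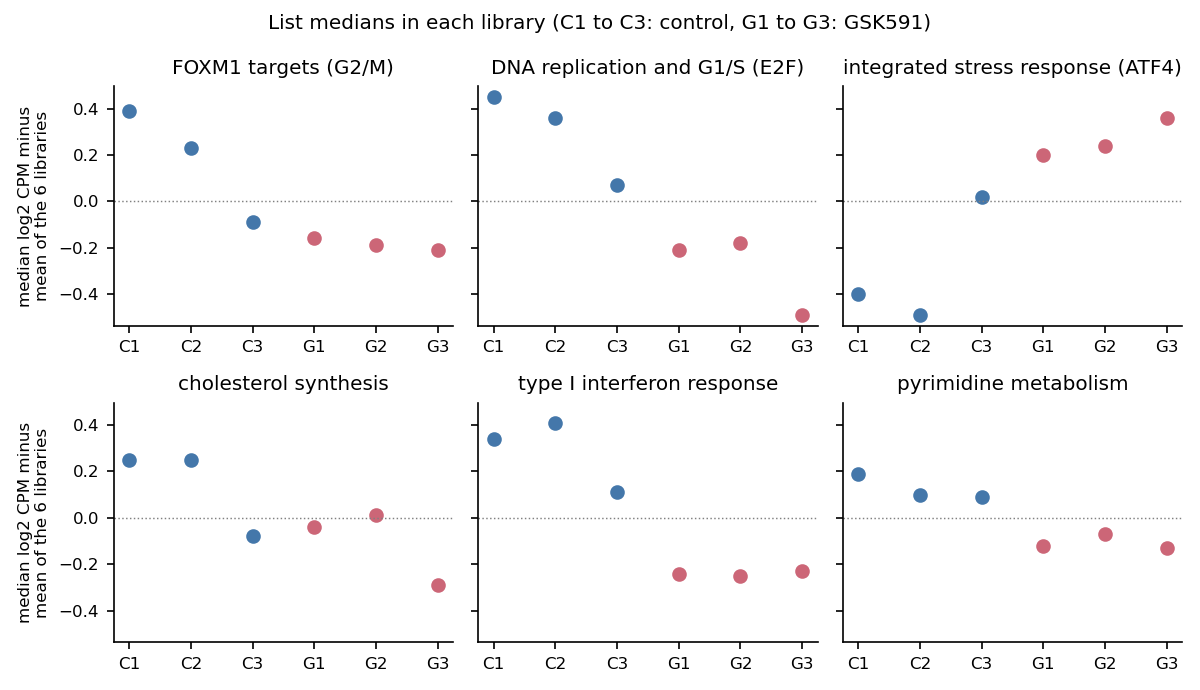
Median log2 CPM of 6 gene lists in each library, relative to the mean of the 6 libraries, with control in blue and GSK591 in red. Control replicate 3 lies between the other controls and the GSK591 libraries for the FOXM1 targets (-0.09) and the replication list (0.07), and close to the other controls for pyrimidine metabolism (0.09).

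Genes of the integrated stress response, which ATF4 drives, were higher with GSK591. Of 31 tested members, 18 rose (19 adjusted over the list alone) and 13 did not pass, with XPOT, a tRNA export factor, at 197 ± 4.74 and 413 ± 40.1 CPM (log2 fold change 1.07, SE 0.09), the glycyl-tRNA synthetase gene GARS1 at 0.83 and the cystine transporter gene SLC7A11 at 1.07. The camera adjusted p was 1.06e-09, against an adjusted p = 0.707 with an estimated correlation. The list median was -0.40, -0.49 and 0.02 in control replicates 1 to 3 and 0.20, 0.24 and 0.36 in GSK591 replicates 1 to 3. Risers numbered 25 without control replicate 3, and 14 without control replicate 1, control replicate 2 or GSK591 replicate 3. The p53 targets went both ways, with 7 of 30 that rose, CDKN1A (0.62), TP53INP1 (0.73) and GDF15 (1.04) among them, and 6 that fell (11 and 6 adjusted over the list alone), such as PLK2 (-0.91), FDXR (-1.23) and BAX (-0.46). The p53 list did not pass camera (adjusted p = 0.561), BAX did not pass on the TPM values (-0.10), and 3 members rose without GSK591 replicate 1.

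Interferon-stimulated genes were lower with GSK591. Of the 46 tested genes of the type I interferon response, 25 fell (28 adjusted over the list alone) and 21 did not pass, with MX1, an antiviral GTPase, at 66.2 ± 10.4 and 23.4 ± 2.00 CPM (log2 fold change -1.50, SE 0.13), IFI35 at -1.32 and IFI27 at -2.18. The list median was 0.34, 0.41 and 0.11 in control replicates 1 to 3 and between -0.25 and -0.23 in the GSK591 libraries. Fallers numbered 29 without control replicate 3 and 17 without control replicate 2. Of 20 genes of antigen presentation by MHC class I, 8 fell (9 adjusted over the list alone), among them the immunoproteasome genes PSMB10 (-1.71) and PSMB8 (-1.13) and HLA-F (-1.45), whose reads can be shared with other HLA genes. The 1 that rose was CD274 (1.09), which codes for the checkpoint ligand PD-L1. In this list 2 rose without control replicate 3, and 5 fell without GSK591 replicate 1. Exons of PSMB8 overlap those of PSMB9 on the opposite strand. Camera adjusted p were 2.42e-08 and 0.00428, against an adjusted p = 0.707 for both with an estimated correlation.

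Transcripts for the ribosome, the mitochondrial genome and cholesterol synthesis were also lower. Of 62 cytosolic ribosomal protein genes, 23 fell (26 adjusted over the list alone) and 39 did not pass, with RPS2 at -0.62, RPL12 at -0.52 and RPS27 at -0.54, genes with many processed copies in the genome that can share reads. Of 13 mitochondrially encoded transcripts 8 fell, MT-CO2 (-0.40), MT-CO3 (-0.41) and MT-ATP6 (-0.36) among them, and these transcripts took 7.92% to 8.12% of the counts in control and 6.66% to 7.02% with GSK591. Of 25 genes of cholesterol synthesis 10 fell, with the same counts adjusted over the list alone for these and the mitochondrial transcripts, such as MVD (-1.44), LSS (-1.04) and FDPS (-0.69), and the regulator SREBF2 rose (0.35), though not without GSK591 replicate 2. Camera adjusted p were 0.000142, 0.0142 and 0.00817 for the 3 lists, against adjusted p = 0.83, 0.817 and 0.83 with an estimated correlation.

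With limma on log2(TPM + 1), 14 ribosomal and 6 cholesterol genes fell. For the ribosomal genes, 10 fell without GSK591 replicate 1 and 11 without GSK591 replicate 3. For the mitochondrial transcripts 5 fell without either of these libraries, and the list did not pass without GSK591 replicate 3 (adjusted p = 0.0661). The cholesterol list had medians of 0.25, 0.25 and -0.08 in control replicates 1 to 3 and -0.04, 0.01 and -0.29 with GSK591. In it 17 genes fell without control replicate 3, 5 without control replicate 2, 6 without GSK591 replicate 1 and 5 without GSK591 replicate 3, where the list did not pass (adjusted p = 0.0619).

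**Figure D3:**
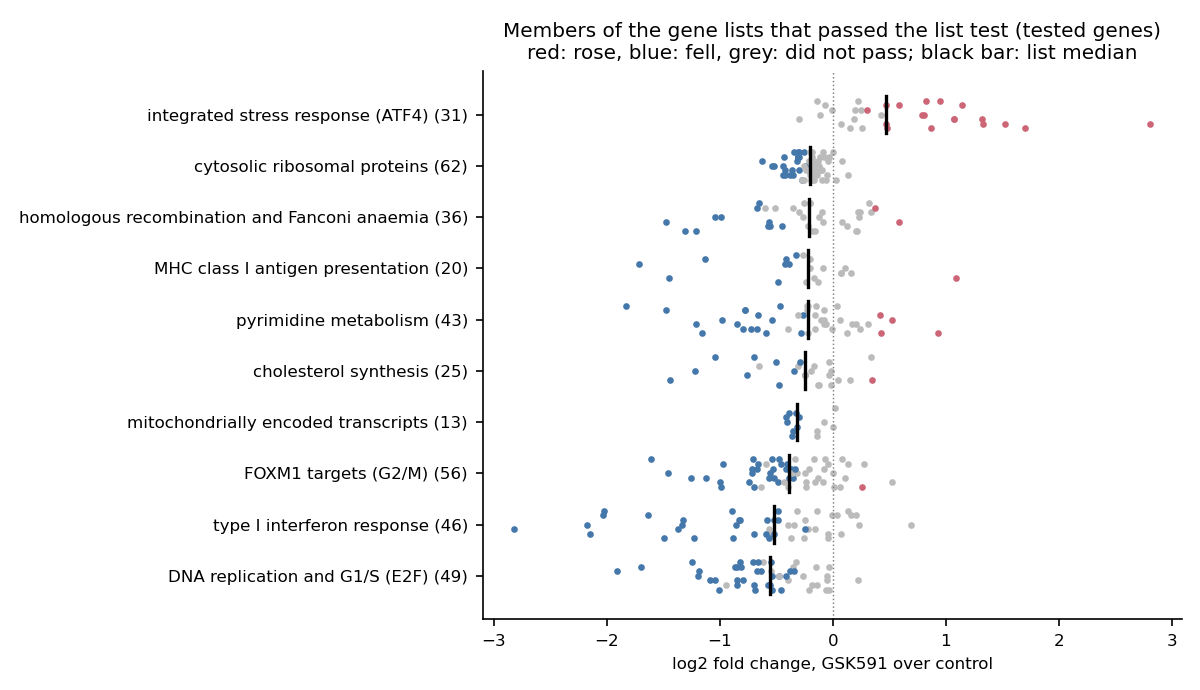
Log2 fold change (GSK591 over control) of each tested member of the 10 gene lists with a camera adjusted p under 0.05, with red for genes that rose, blue for genes that fell, grey for genes that did not pass and a black bar at the list median. The stress response list lies to the right (median 0.47) and the other 9 to the left, down to -0.55 for the replication list.

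The largest single changes were in genes outside these lists for the most part. ACADVL, which starts the mitochondrial oxidation of very long-chain fatty acids, fell from 179 ± 20.1 to 26.1 ± 4.15 CPM, a level 6.87-fold lower (log2 fold change -2.78, SE 0.13, adjusted p = 5.1e-07 in the edgeR quasi-likelihood test). HPS1, part of a complex for lysosome-related organelles, fell from 52.6 ± 9.05 to 7.53 ± 0.35 CPM (-2.80, SE 0.15), and NAPRT, an enzyme of NAD synthesis from nicotinic acid, fell from 54.2 ± 4.93 to 8.68 ± 0.60 CPM (-2.64, SE 0.13). The other 7 of the 10 largest falls were SFXN2 (-2.86), RAB26 (-2.85), SPAG4 (-2.81), HSD17B8 (-2.75), OPLAH (-2.70), MSLN (-2.65) and ANO9 (-2.56). ACADVL lies on chromosome 17 from 7217125 to 7225273, HPS1 on chromosome 10 from 98416198 to 98446947 and NAPRT on chromosome 8 from 143574785 to 143578649, all on GRCh38. On the opposite strand, exons of ACADVL overlap those of DLG4, those of NAPRT overlap AC067930.5 and AC067930.6, and those of OPLAH overlap SMPD5, so these values are uncertain.

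The largest rise was in RAB39B, a small GTPase gene, with 10 counts over the 3 control libraries and 391 over the GSK591 libraries, a ratio of 39.1 (95% counting interval 21 to 82.1, counting error only). MAP1B, which codes for a microtubule-binding protein, rose from 6.43 ± 2.13 to 24.6 ± 2.81 CPM (log2 fold change 1.93), the lipase inhibitor gene ANGPTL4 from 1.95 ± 0.45 to 9.96 ± 1.07 CPM (2.35) and the calcium-binding protein gene S100P from 1.40 ± 0.13 to 7.78 ± 1.89 CPM (2.47). ADM2 (2.81), TP53AIP1 (2.48), MTCP1 (2.04), FMC1 (1.93), GPX2 (1.87) and P2RY11 (1.85) completed the 10. The exons of MTCP1, FMC1 and P2RY11 overlap those of CMC4, LUC7L2 and PPAN on the same strand, so their values are uncertain.

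Over all genes, 3860 of the 12491 tested changed, 1778 up and 2082 down, in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. At least 2-fold changes were found in 665 genes, of which 156 rose and 509 fell. The groups did not overlap for 5872 genes (47.0% of those tested), where chance gives 10%. Falls made up 53.9% of the changed genes here and 57.1% with upper-quartile scaling of the counts, against 39.2% with limma on the deposited TPM values, where unit, scaling and test all differ. Leaving out GSK591 replicate 1 or 3 gave 2467 and 2565 changed genes, of which 1013 and 1051 rose, and 1088 rose without control replicate 2.

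Terms of the deposited annotation that passed included splicing and the basement membrane. Genes of the spliceosome pathway were higher, with 51 of 129 that rose and 6 that fell (camera adjusted p = 8.55e-05, and adjusted p = 1 with an estimated correlation). Genes of the basement membrane were lower, with 32 of 69 that fell and 4 that rose (camera adjusted p = 1.08e-05, and adjusted p = 1 with an estimated correlation). Of the 3039 terms, 37 passed as lower and 14 as higher, and 0 passed with an estimated correlation. Terms were tested in the main fit alone, not with the GC correction, on the TPM values or with a library left out. The fixed lists of Sm and SMN genes and of SR proteins and hnRNPs did not pass camera (adjusted p = 0.259 and 0.641). The pyrimidine metabolism pathway of the annotation, with 16 of 49 that fell and 4 that rose, did not pass (adjusted p = 0.073).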

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

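The alternatives were planned before the data were examined, except the GC correction. FOXM1 kept its direction and its side of the threshold in every one run, and the count of changed genes lay within 1.5 times of 3860 except without GSK591 replicate 1 or 3. Leaving out 1 library in turn gave 2467 to 4478 changed genes, 1013 to 2187 risen genes and a PRMT5 log2 fold change of 0.268 to 0.348. The 2-library groups leave fewer residual degrees of freedom, and the cause beyond that was not tested. On log2(TPM + 1), 362 genes changed at least 2-fold and 251 fell at least 2-fold, against 665 and 509, and RRM2B turned to -0.18 on both TPM scales. The pseudocount lowers the fold of weakly expressed genes but does not turn a sign. Count and TPM of a gene differ by its effective length and a factor per library, so the turn of RRM2B lies mostly in its effective length. RRM2B was not among the genes whose effective length passed the test for a shift, and what lies behind the turn was not tested. With an estimated correlation in camera the pyrimidine list had an adjusted p of 0.707 and the FOXM1 list 0.817. The estimated correlation was 0.0537 and 0.44 for these 2 lists, against 0.01 preset. By fry the FOXM1 list had 0.0713, the repair list 0.118, the ribosomal list 0.0825 and the cholesterol list 0.098, where these calls were lost. The pyrimidine list passed fry (adjusted p = 0.0171). Some lists passed fry and not camera, namely purine synthesis, the basal keratinocyte list and TGF-beta (0.0171 each) and apoptosis regulators (0.00166). With the replicate number as a block 4268 genes changed and the apoptosis list passed, the 1 call it changed among the results of the text. The deviations of same-numbered libraries correlated by 0.17, 0.069 and 0.12, so the numbers were not taken to pair the samples, though each library correlated best with its own number, a hint from the data and not the design. With the GC correction 4765 genes changed, and 3428 of the 3860 were among them with the same sign. Of 230 results, 23 lost their call without GSK591 replicate 3, 20 without control replicate 2, 19 and 16 without GSK591 replicates 1 and 2, 4 without control replicate 1 and 6 with the GC correction. On either TPM scale 9 lost their call, among fewer results, since camera was not run on the lists there. On simulated counts with this depth, spread and number of libraries 57% of the 1.5-fold changes were found, so changes of that size can be missed. Only 200 of the 12341 simulated genes changed, against 3860 in the data, and the simulated genes varied independently of each other. The data hold deviations shared between genes, such as the correlation of 0.44 in the FOXM1 list. The shares found and false may therefore differ here. Depth was not varied.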

Other observations

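The tests of where control replicate 3 lay and of short introns among genes of like GC content were chosen only after the results were seen. So were the GC correction itself, the comparison of read-through genes and the exact interval for transcript usage. The judgement that the test of scaling moved too little to decide was also made then.

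Genes of the basal keratinocyte list went both ways. The integrin gene ITGA3 fell from 1320 ± 224 to 304 ± 20.9 CPM (log2 fold change -2.12, SE 0.12), COL7A1, the collagen of anchoring fibrils, fell by 1.94 and ITGB4 fell by 1.22, whereas KRT14 rose from 25.6 ± 2.17 to 74.9 ± 9.44 CPM (1.55, SE 0.12), as did the integrin gene ITGA2 (0.90) and BMI1 (0.72). Of 26 tested genes of the basal keratinocyte list 6 rose and 9 fell, and it did not pass camera (adjusted p = 0.145, and 0.016 without control replicate 3). Among 34 mesenchymal and invasion genes 9 rose, PLAU (log2 fold change 0.84) and MMP3 (1.70) among them, and 8 fell, LOXL2 (-0.97) first (adjusted p = 0.147). GRHL3, a regulator of epidermal differentiation, had 3 counts over the control libraries and 94 with GSK591, a ratio of 31.3 (95% counting interval 10.4 to 154). The keratinocyte differentiation list had 6 of 29 that rose and 7 that fell (adjusted p = 0.933), the junction list 7 and 5 of 29 (0.522) and the TGF-beta list 1, SKIL, and 5 of 19 (0.425). For keratinocyte differentiation, 3 rose without GSK591 replicate 1 and 2 without GSK591 replicate 3, and 2 fell without control replicate 2 or GSK591 replicate 3. For the junction list, 4 rose without GSK591 replicate 1 or 3, and 3 fell without control replicate 2 or any 1 GSK591 replicate. In the TGF-beta list 2 rose without control replicate 1. On the TPM values risers and fallers numbered 11 and 4 for the mesenchymal list, 7 and 3 for keratinocyte differentiation, 7 and 2 for junctions and 2 and 4 for TGF-beta.

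Metabolic and inflammatory lists went both ways. In purine synthesis 2 of 21 rose and 4 fell, ATIC (-0.85) and IMPDH2 (-0.72) among them (camera adjusted p = 0.217). In serine and one-carbon metabolism 5 of 18 rose, such as MTHFD2 (0.64), and 5 fell (0.944). The NF-kB list had 5 risers and 6 fallers of 35, with C3 lower (1420 ± 230 to 580 ± 45.8 CPM, log2 fold change -1.29) and IL24 higher (1.39, adjusted p of the list 0.944). NRF2 targets had 7 and 4 of 25, with TALDO1 at -1.24 and AKR1B10 at 1.73 (0.598), glycolysis and hypoxia 6 and 9 of 35 (0.561), fatty acid synthesis 1, GPAM, and 5 of 17 (0.425), autophagy and lysosome 6 and 11 of 31 (0.0863, and 0.0203 without control replicate 1), ER chaperones 6 and 7 of 22 (0.998), ribosome biogenesis 4 and 6 of 45 (0.641) and apoptosis regulators 7 and 2 of 32 (0.055, 0.0277 without control replicate 3 and 0.0458 without GSK591 replicate 1). Nuclear genes of oxidative phosphorylation had 7 risers and 4 fallers of 47 (0.37), but 19 and 2 on the TPM values, where ribosome biogenesis had 10 and 5, fatty acid synthesis 3 and 4 and apoptosis regulators 8 and 0 by limma. For purine synthesis, 1 rose without control replicate 2 or any 1 GSK591 replicate, and 8 fell without control replicate 3. One-carbon risers numbered 3 without control replicate 1 or GSK591 replicate 2 and 2 without control replicate 2 or GSK591 replicate 3. Of the ER chaperones, 2 rose without control replicate 2 or GSK591 replicate 3 and 3 without GSK591 replicate 2, and 4 fell without control replicate 2 or GSK591 replicate 1. Without control replicate 2, GSK591 replicate 1 or GSK591 replicate 2, 2 genes of ribosome biogenesis and 2 of oxidative phosphorylation rose, and 2 of oxidative phosphorylation fell when any 1 of these or GSK591 replicate 3 was left out. Apoptosis risers numbered 4 without control replicate 2 and 3 without GSK591 replicate 3, with 1 faller when any 1 library other than control replicate 3 was left out, and 3 genes of fatty acid synthesis rose without control replicate 3.

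For the lists closest to the drug's target, 7 of 32 genes of the Sm and SMN complexes rose and 3 fell (camera adjusted p = 0.259), with SMN1 at 0.58, whose reads can be shared with its copy SMN2. On the TPM values 11 rose and 2 fell. Without control replicate 2, GSK591 replicate 1 or GSK591 replicate 2, 4, 2 and 1 rose, and 1 fell without GSK591 replicate 1 or 3. SR proteins and hnRNPs had 7 and 5 of 33 (0.641), with HNRNPA1 at -0.80. In that list 11 rose without control replicate 1 and 3 without control replicate 2, GSK591 replicate 1 or GSK591 replicate 2. Its fallers numbered 11 without control replicate 3, 3 without GSK591 replicate 1 and 2 without control replicate 2 or GSK591 replicate 3. Of 12 arginine methyltransferases and partners 2 rose, PRMT5 and RIOK1 (0.51), and 1 fell, PRMT1 at -0.34 (0.944). Among reference genes 4 of 14 fell, GAPDH by 0.48 (0.354), and 2 fell without GSK591 replicate 1 or 3, while 2 rose and 3 fell on the TPM values. Replication-dependent histones had 2 of 9 that fell, H2BC11 and H2AC6 (0.522), with 1 riser and 1 faller on the TPM values. Only 9 of the 22 listed histones could be tested in these poly(A)-selected libraries. H2BC11 had a mean of only 20.7 counts in control and 5.7 with GSK591. Neither of 2 tested germline genes passed edgeR's test, while 1 rose adjusted over the list alone (0.561). RIOK1 did not pass without GSK591 replicate 1, 2 or 3, PRMT1 without GSK591 replicate 1, H2BC11 without GSK591 replicate 1 or 3, or H2AC6 without control replicate 2, GSK591 replicate 1 or 3. Markers of other cell types were few: 1 of 8 fibroblast markers fell, FBLN1 (-0.62, adjusted p of the list 0.522), but 6 of 9 fell without GSK591 replicate 1 (8.07e-06), and on the TPM values 1 rose and 1 fell. Of 5 leukocyte markers LAPTM5 and CD14 rose and CD68 fell (0.81), and of 4 endothelial markers CDH5 fell (0.836), though not on the TPM values. CD14 did not pass without control replicate 1 or 2 or GSK591 replicate 2 or 3, or CDH5 without control replicate 2 or GSK591 replicate 1. Adjusted over the list alone, the counts of risers and fallers were the same except for arginine methyltransferases (2 and 2), ribosome biogenesis (4 and 5), keratinocyte differentiation (7 and 9), the basal list (6 and 10), glycolysis (6 and 10), oxidative phosphorylation (6 and 3) and autophagy (7 and 14). Median, mean and test differed in sign for one-carbon metabolism, ER chaperones, arginine methyltransferases, keratinocyte differentiation and leukocyte markers.

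The direction of change went with GC content across the data. Over 12225 genes with introns, log2 fold change and GC content had a Spearman rho of -0.323. All risen genes had a median GC content of 43.6% and all fallen genes 54.2%. Whether this trend came from the libraries or the treatment was not tested, so list and term calls may hold part of it. Falls of at least 2-fold outnumbered rises by 3.26 to 1. The genes fallen at least 2-fold had a median GC content of 55.7% against 48.3% for all, and a median intron of 873 bases against 2042. After a GC trend was removed within each library the ratio was 2.52, so a GC bias of this form may explain part of it and, in these libraries, not the whole. The 95% interval of 2.10 to 3.03 counts the called genes as independent and holds no spread between libraries. With 1 library left out and no GC correction, the ratio ranged from 2.25 (without control replicate 3) to 4.25 (without GSK591 replicate 3). Scaling stays open: the planned test gave 3.24 with DESeq2 factors and 3.54 with upper-quartile scaling, but these moved the median of all genes by only 7e-04 and -0.018, while limma on the TPM values gave 1.80 to 2.26, and a uniform shift of 0.11 would bring the ratio counted by fold alone, with no test, from 2.71 to 1.5. The planned test of intron length found a partial rho of 0.017 (0.002 to 0.034) across 12225 genes, against a gradient. The later test took the fallers themselves, with the fifth of shortest introns picked after its count of 235 was seen. It gave an odds ratio of 2.69 (2.16 to 3.34) at like GC content and expression, and 1.365 (0.883 to 2.109) for 2-fold rises. Short introns may thus mark part of the fallers, a hypothesis found and tested on the same libraries.

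Control replicate 3 lay, by the median, partway from the other controls to GSK591 in the list members that changed without it. Its position was 54.3% of the way (95% interval 26.6 to 78.4) for the FOXM1 targets, 43.0% (21 to 60.6) for the replication list and 26.6% (-11.7 to 114) for the repair list. It was 55.0% (34.4 to 62.5) for the stress response list and 33.6% (14.8 to 52.7) for the interferon list. A treated or mixed sample under its label would lie partway in the other strongly changed genes too. Over 624 genes changed at least 2-fold outside the FOXM1, replication, repair and stress lists, interferon genes included, its median position was 0.7% (95% interval -2.8 to 4.6). For the 92 of them among the 100 smallest adjusted p it was -7.2% (-11.3 to -3.9). This argues against a treated or mixed sample as the whole cause. The list members were taken at any fold and the 624 genes at 2-fold or more, so their positions are not compared at a like size of change. The libraries that chose the genes also set the ends of the scale. All these intervals resample genes within 1 library and hold no spread between libraries. The position of the interferon genes stays unexplained. A difference in growth state between the control libraries may remain and was not tested.

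The ratio of count to TPM gives each gene's effective length, which moves with the transcripts used. It shifted in 11 of 10533 genes, in MRPS25 (log2 0.73), MROH1 (-0.58) and ARRB1 (0.42) among others, which were chosen after their values were seen. Fragment length that differs between the libraries would shift single-transcript genes as often. In these 0 of 508 shifted, a ratio of 0 to the share in the 10025 genes with several transcripts, but the limit that this allows (6.59) leaves the question open. By limma 1527 genes had an unadjusted p under 0.05.

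For 49 read-through genes, 7 rose and 5 fell, with a median log2 fold change of 0.15, at percentile 97.4 of 10000 random sets matched on expression. The median difference from their partner genes was 0.20 (95% interval -0.14 to 0.42). This comparison was not planned before the values were seen, so the percentile only describes the set and is no test of it.

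There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 3860 changed genes and 665 changed at least 2-fold, where the highest of the others gave 0 and 0 by edgeR, with 48 to 487 genes at an unadjusted p under 0.05. It was the 1 split of 10 with so many, for both counts. PRMT5 had an unadjusted p of 0.0042 against 0.14 in the next split, and FOXM1 5.3e-06 against 0.21, each the smallest in 1 split of 10. For the pyrimidine list 2 of 10 splits had a camera p as small (0.00067 for the real one, 9.6e-05 for the smallest other), and for the FOXM1 targets 4 of 10 (3.1e-07 against 4.5e-19). The 3 other splits for the FOXM1 targets each set control replicates 1 and 2 with 1 GSK591 library against control replicate 3 with the rest, which points to a structure of the samples.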
